A study of Mus musculus with 6 samples.

How the data were processed

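RNA sequencing libraries were made from whole livers of 12-day-old mice, per the labels. In 3 samples, Tbx21 carried floxed alleles together with a Cre driven from Foxp3, and 3 control samples had the Cre and reporter alleles alone. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the mm10 build. Only these names and versions were read, so the purpose of each is not given here. The deposited table, which its name describes as FPKM values per gene, held 6 columns of values under running numbers. None of these 6 column names occurs in the title or description of a sample, so no column could be tied to a sample or a genotype. Assigning the columns by their order or by their values would have been a guess. All 6 columns were therefore left unused. No expression level, library depth or replicate spread was computed, and the genotypes were not compared.

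The gene annotation that the authors deposited beside the values (identifier, symbol, chromosome, start, end, strand, length and biotype, per the file headers) was read with Python 3.11.15. Each gene identifier was looked up in GENCODE release M21, an annotation of GRCm38, the assembly also called mm10. A gene was counted as being at the same place where chromosome, start, end and strand were identical. Its length was counted as equal where it matched, to the base, the number of positions covered by the exons of any of its M21 transcripts. The genes described individually were those fixed by name before the data were examined. The 47 gene lists fixed at the same time were matched to the table by symbol. Symbols without a row were looked up among the names of the RefSeq annotation of GRCm38.p6. The comparison with GENCODE M21 and the lookup of other names were chosen after the table had been seen. The test fixed in advance, a limma fit of log2 values on genotype with its alternatives, was not run.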

Results

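The study profiled whole-liver RNA from 12-day-old mice to compare animals with and without Tbx21 in Foxp3-expressing cells. Tbx21 encodes T-bet, a transcription factor of interferon-gamma-producing lymphocytes, and Foxp3 is the lineage factor of regulatory T cells. The labels gave 3 samples with floxed Tbx21 and 3 control samples. The 6 columns of the expression table carried only running numbers, and none could be matched to a sample. No comparison of the genotypes was therefore made, and no expression value is reported for any gene. What follows describes the genes that the table covered and where they lie.

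The table covered 54532 genes, of which 22046 were protein-coding, 9497 were processed pseudogenes and 5559 were long intergenic non-coding RNAs. It also listed 2207 microRNA genes and 1507 small nucleolar RNA genes. The table lists a length for each gene, which for most genes equalled the number of positions covered by its exons in GENCODE M21. The listed length was set beside the gene's extent on the chromosome only for the genes fixed by name. The median of this listed length was 3422 bp for protein-coding genes, 1038 bp for long intergenic non-coding RNAs, 89 bp for microRNA genes and 127 bp for small nucleolar RNA genes. Altogether 6793 genes, 12.5% of the table, had a listed length under 200 bp.

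Tbx21 (ENSMUSG00000001444), the targeted gene, was listed on the minus strand of chromosome 11 from 97098071 to 97115331 (mm10). Its listed length of 2488 bp equalled the total of its annotated exons in GENCODE M21, within a gene that spans 17261 bp. Foxp3 (ENSMUSG00000039521), whose locus drives the Cre, was listed on the plus strand of chromosome X from 7579676 to 7595243. Foxp3 was the exception among the genes fixed by name. Its chromosome, start, end and strand were not all identical to those in GENCODE M21. Its listed length of 3989 bp was below the 4577 bp of exons annotated there. Ifng, the interferon-gamma gene (ENSMUSG00000055170), lay on chromosome 10 from 118441046 to 118445892 with a length of 1295 bp.

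Both interferon-inducible chemokine genes fixed by name lay on the minus strand of chromosome 5. Cxcl9 (ENSMUSG00000029417) ran from 92321347 to 92328079 with 3016 bp of exons, and Cxcl10 (ENSMUSG00000034855) from 92346638 to 92348889 with 2252 bp. For Cxcl10, the exons of its annotated transcripts together covered the whole span of the gene, also 2252 bp. The albumin gene Alb (ENSMUSG00000029368), the main plasma protein gene of hepatocytes, ran from 90460897 to 90476602 on the plus strand of the same chromosome. Afp (ENSMUSG00000054932), the alpha-fetoprotein gene of fetal hepatocytes, followed it from 90490737 to 90508907. Cyp7a1 (ENSMUSG00000028240), the rate-limiting enzyme of bile acid synthesis, lay on chromosome 4 from 6265612 to 6275633 with 4174 bp of exons.

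Of the 54532 identifiers, 54495 were present in GENCODE M21 and 37 were not. Among the 54495 shared genes, 53548 (98.3%) had the same chromosome, start, end and strand in both annotations. The listed length equalled the union of the M21 exons for 53411 of the 54495 shared genes (98.0%). Of the 957 distinct symbols in the 47 gene lists fixed in advance, which covered immune and liver cell types, metabolic and stress pathways and markers of other tissues, 952 occurred in the table. Every member was present for 42 lists, including the 15 regulatory T cell markers, the 32 interferon-gamma-induced genes and the 34 mature hepatocyte genes. The 21 exocrine pancreas markers and the 15 skeletal muscle markers were also all present. A row shows that a gene was annotated, not that it was detected in liver. The 5 symbols without a row were Ahsp, G6pc1, C5, Ccn1 and Bmal1. Matching was by symbol alone, and a gene can be present under another name. RefSeq names pair Bmal1 with Arntl, C5 with Hc and Ccn1 with Cyr61, and each of these other names had a row in the table. The same lookup also returned Ccna2, the cyclin A2 gene and a different gene, for Ccn1, so a shared name alone does not identify a gene. The RefSeq names gave no other name with a row for Ahsp or G6pc1. G6pc, which the lookup did not return and which is known from general knowledge as the older symbol of G6pc1, was itself a member of the same list and had a row.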

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

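The match with GENCODE M21 and its only alternative, a restriction to protein-coding genes, were both chosen after seeing the data. Both shares were lower among protein-coding genes. The share at the same place was 96.4%, against 98.3% of all shared genes. The share with an equal length was 95.8%, against 98.0%. The cause of the lower shares was not tested. Neither the gene list tests nor any variant of the genotype comparison (pseudocount, filter, scaling, leaving out each sample) was run. No column of values could be matched to a sample. No paired analysis was possible because the columns carry no replicate number that the labels share. The labels also do not say that the replicate numbers pair animals. Depth was not assessed, since the columns of values were not used.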
